A study of Mus musculus with 6 samples.

How the data were processed

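The series holds RNA sequencing of mouse CD8+ T cells from 6 libraries, 3 of control cells and 3 of cells given acetate. CD8+ T cells are the lymphocytes that kill infected or tumour cells. Per the labels' protocols, they were taken from spleen by positive magnetic selection and grown for 72 h on plates coated for 24 h with anti-CD3 at 5 µg/mL and anti-CD28 at 2 µg/mL, antibodies that stimulate the T cell receptor and its costimulator, in medium with IL-2 at 30 U/mL. The labels give the treatment as acetate for 48 h at a concentration read here as 5 mmol/L, because its unit is written in an unusual way. They do not say when in the 72 h of culture acetate was added. The series' design text speaks of cells before and after acetate while the labels name treated and control cells, so the 2 groups could differ in time in culture as well as in acetate. Each library's group and number come from its title. The labels do not say whether the 3 libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

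The deposited table gives FPKM (fragments or reads per kilobase of gene, scaled to the library total) for 41095 genes. Per the labels' protocols, total RNA was made into libraries with a TruSeq kit and sequenced as paired ends on an Illumina NovaSeq instrument. Reads were trimmed with cutadapt 1.18 and aligned with HISAT2 2.1.0, per the submitters' processing notes, which name the build mm10. The counting tool and its handling of strand and of reads shared between genes are not given in the sources used here. The gene identifiers in the table are those of the C57BL/6NJ strain annotation, and the positions beside them are not mm10 positions. Of 18933 genes matched by symbol to an mm10 annotation, 99.85% lay on the same chromosome but 0.81% overlapped the mm10 position, with a median offset of 3223.6 kb. Positions are therefore printed as the table gives them. The table held no rows on the Y or mitochondrial chromosome, 10687 rows had no symbol, and 1 line held no values.

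FPKM values multiplied by gene length were whole multiples of a single step in each library. With a tolerance of 0.01 reads, 100.0% of values were whole reads, from which 31098394 to 39140711 reads per library were recovered. The library totals that the authors' FPKM imply were 30623316 to 39141865, and the ratio of recovered reads to that total ran from 0.974 to 1.016. Between 64.2% and 65.7% of values of up to 40 reads were even, against 49.5% to 50.8% of values above 200 reads. The ends of a read pair were thus apparently counted separately, and read numbers overstate the number of independent fragments. The 10 most abundant genes took 3.77% to 4.07% of the reads of a library.

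The choices that follow were made before the data were examined, except where stated. Genes with a mean of at least 1 FPKM over the 6 libraries were kept, which left 10867, of which 9579 were protein-coding. Values were transformed as log2(FPKM + 1) and compared with limma 3.58.1 in R 4.3.3, with an empirical Bayes trend on abundance and group as the only term. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes named log2 are on the log2(FPKM + 1) scale, which understates the change of genes of low abundance. Fold values without that name are ratios of mean FPKM. Means are given with the SD over 3 libraries.

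Lists of genes were compared with the remaining genes by limma's camera with a preset correlation between genes of 0.01. Of 41 lists, 37 had at least 3 tested members. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in one direction, were run beside it. With an estimated correlation, camera takes its degrees of freedom from the libraries and not from the number of genes, which alone raises p. Genes named in the text followed a fixed rule. It took the 12 protein-coding genes with the largest rise and the 12 with the largest fall among those past the threshold whose acetate and control values did not overlap. It added a panel of 26 genes whatever their values, the 2 to 4 members of lowest p of each list past the threshold, and up to 2 members past the threshold of each other list. Genes and lists named outside this rule are said to have been chosen after their values were seen. Some genes under the rule are not reported here.

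The test was tried on simulated data for 10867 genes with 200 changed genes, for the acetate against control comparison. It recovered 59.7% of the smallest changes simulated, which were under 1.5-fold, 92.5% of 1.5-fold and 93.9% of 2-fold, and 7.3% of the genes called had not been changed. Of 30 random lists, camera called 0. Genes were simulated independently of each other, so this cannot show whether a preset correlation of 0.01 suits real lists. The simulation also drew reads rather than read pairs and changed a far smaller share of genes than the 38.9% called in the data. Its rates of recovery and of false calls may therefore not hold for the data. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 3.27 to 5.79 within groups and 17.69 to 21.22 between groups, so that no pair was treated as 1 library sequenced again.

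Alternatives set beforehand were pseudocounts of 0.1 and 5, no filter on low values, a filter at 5 FPKM, median centring, quantile normalization, rescaling to TPM, the replicate number as a block, leaving out each library, array weights, no abundance trend, a minimum change and protein-coding genes only. Limma's voom on the recovered reads, cyclic loess normalization, removal of trends on GC content and gene length, lists extended with symbols from gene descriptions, lists and single genes over protein-coding genes only, and a run without pseudogenes and unnamed genes were added after the data were seen. So were 4 further lists, which were also run without members of the fixed lists and the genes of largest change. GC content was known for 91.3% of the genes tested. Count tests planned for a table of counts were not run, because the table holds FPKM.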

Results

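The data were FPKM values of splenic mouse CD8+ T cells stimulated through CD3 and CD28 in culture, from 3 control libraries and 3 libraries of cells given acetate, a short-chain fatty acid. Control libraries held 32195815, 35713993 and 35138058 recovered reads and acetate libraries 39140711, 35037986 and 31098394. The series title ties the experiment to cytotoxic CD8+ T cells in melanoma, and the comparison asks which transcripts differ between acetate-treated and control cells. The labels give 72 h of culture for both groups, but the design text speaks of cells before and after acetate. Whether both groups had spent the same time in culture when they were collected therefore stays open.

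With acetate, 23 of 24 tested genes of the amino acid and ATF4 list fell, and 22 of 24 S phase, 19 of 23 cholesterol synthesis and 17 of 24 ribosome biogenesis genes rose. These 4 lists passed by camera with a preset correlation, but with an estimated correlation they had adjusted p = 0.16, 0.16, 0.2 and 0.23. Trib3, a pseudokinase induced in that stress response, fell 5.02-fold from 31.8 ± 1.69 to 6.33 ± 0.627 FPKM (SD, n = 3 per group), and Ctla2b, a relative of cysteine protease inhibitors, rose 2.64-fold from 7.65 ± 0.411 to 20.2 ± 1.37 FPKM. Among cytotoxic genes Gzma fell 2.38-fold while Gzmb rose from 2160 ± 17.8 to 2703 ± 64.1 FPKM. In all, limma called 2393 genes higher and 1836 lower with acetate among 10867 tested. Most changes were small, with a median log2 change of 0.26 among genes that rose and -0.30 among those that fell, and 11 genes rose and 38 fell by at least 1 on the log2 scale. The 3 acetate values lay all above or all below the 3 control values for 5640 genes, or 51.9% against 10% by chance. Correlations of log2 values across genes were 0.9925 to 0.9934 within groups and 0.9835 to 0.9858 between them, over genes that are not independent replicates. Higher genes were 56.6% of the calls as deposited and 36.4% after rescaling to TPM.

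Of the 12 largest falls, 4 were in members of the amino acid and ATF4 list, Trib3, Ddit3, Nupr1 and Cth. Trib3 lies on chromosome 2 from 161450457 to 161457704 in the table's C57BL/6NJ positions. Ddit3, which encodes the stress transcription factor CHOP, fell from 34.1 ± 2.06 to 10.1 ± 0.315 FPKM (limma adjusted p = 9.11e-06). Nupr1, a stress-induced transcription regulator, fell from 5.82 ± 0.488 to 1.11 ± 0.285 FPKM. Cth, the enzyme that releases cysteine from cystathionine, fell from 32.5 ± 1.09 to 12.99 ± 0.38 FPKM. The amino acid transporters Slc7a3, Slc1a4 and the glycine transporter Slc6a9 fell 2.74-fold, 2.61-fold and 3.67-fold. Of the 24 tested members of the amino acid and ATF4 list, 23 fell and 1, the cystine transporter Slc7a11, named after its values were seen, rose, with the same counts adjusted over the list alone. Chac1, which degrades glutathione, fell from 9.81 ± 0.285 to 4.27 ± 0.305 FPKM. The list was lower by camera (adjusted p = 1.42e-14), with adjusted p = 0.16 with an estimated correlation. The rise of Slc7a11 by 0.23 on the log2 scale was lost (adjusted p = 0.0722 to 0.114) when any control library or acetate replicate 2 was left out.

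Outside that list, Soat2, which esterifies cholesterol, fell 4.07-fold from 19.1 ± 0.658 to 4.68 ± 0.247 FPKM and lies on chromosome 15 from 108182510 to 108195317. Cyb5r1, a cytochrome b5 reductase, fell from 24.8 ± 0.169 to 8.51 ± 0.634 FPKM. Angptl6, a secreted angiopoietin-like protein, fell from 25.2 ± 2.21 to 8.69 ± 0.794 FPKM, and Avil, an actin-binding protein, fell from 2.80 ± 0.154 to 0.562 ± 0.144 FPKM. An unnamed gene, MGP_C57BL6NJ_G0016624, fell from 7.97 ± 3.96 to 2.17 ± 1.22 FPKM (adjusted p = 0.0212). That call was lost without control replicate 1 or 2 or acetate replicate 2 or 3 (adjusted p = 0.0618 to 0.0689).

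**Figure D1:**
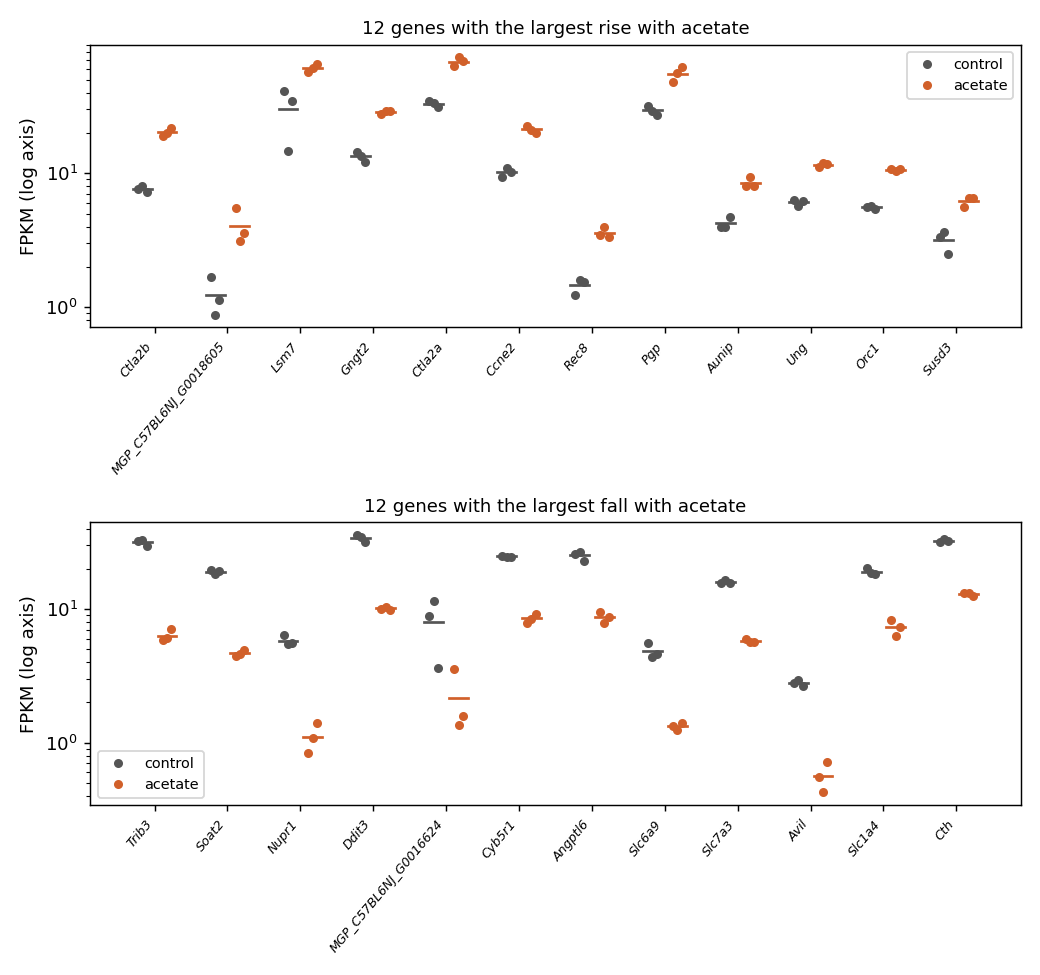
FPKM of the 12 protein-coding genes with the largest rise (top) and the 12 with the largest fall (bottom) with acetate, on a log axis. Each point is 1 library, bars are means of 3 libraries, and groups do not overlap for any gene shown, such as Trib3 with 29.9 to 33.1 FPKM in control and 5.92 to 7.05 FPKM in acetate libraries.

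Among the largest rises, Ccne2, which encodes cyclin E2, rose from 10.2 ± 0.793 to 21.3 ± 1.20 FPKM, Orc1 of the origin recognition complex from 5.57 ± 0.182 to 10.6 ± 0.217 FPKM, and Ung, the uracil-DNA glycosylase, from 6.08 ± 0.375 to 11.6 ± 0.393 FPKM. Of the 24 tested members of the S phase list 22 rose, and all 24 did when adjusted over the list alone. Ccne1 rose from 28.5 ± 1.33 to 48.6 ± 1.48 FPKM, and the helicase subunits Mcm4 and Mcm2 rose from 50.4 ± 0.835 to 78.9 ± 3.03 FPKM and from 21.3 ± 0.75 to 33.0 ± 1.22 FPKM. The list was higher by camera (adjusted p = 3.03e-12), with adjusted p = 0.16 with an estimated correlation. Of 26 tested G2 and M phase genes, 3 rose and 4 fell, or 2 and 4 adjusted over the list alone, and the list was not past the threshold (adjusted p = 0.474). Cdk1 rose from 14.8 ± 0.0689 to 18.1 ± 0.41 FPKM and Kif23, a mitotic kinesin, fell from 13.9 ± 0.992 to 11.1 ± 0.204 FPKM. Of 37 listed replication-dependent histone symbols, older and newer names of the same genes among them, 13 were in the table and 4 were tested. Those 4 did not pass (limma adjusted p of 0.464 or more), at a median log2 change of 0.141, and are too few to bear on the S phase rise.

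Other large rises were in genes of varied function. Ctla2b and its neighbour Ctla2a, on chromosome 13 from 62481033 to 62483117 and from 62519826 to 62522296, rose 2.64-fold and 2.06-fold. They are similar in sequence, and the share of reads between them is uncertain. Gngt2, a G protein gamma subunit, rose from 13.4 ± 1.14 to 28.9 ± 0.802 FPKM, and Rec8, a meiotic cohesin subunit, rose from 1.46 ± 0.192 to 3.61 ± 0.329 FPKM. Pgp, the phosphoglycolate phosphatase, rose 1.88-fold, Aunip 2.00-fold and Susd3 1.98-fold. The unnamed gene MGP_C57BL6NJ_G0018605 rose from 1.23 ± 0.408 to 4.07 ± 1.26 FPKM, from a mean of 15 and 50 reads. Lsm7, part of an RNA-binding ring, rose from 30.1 ± 13.8 to 61.2 ± 4.02 FPKM, with control replicate 2 at 14.7 FPKM. Its call (adjusted p = 0.0303) was lost when any acetate library was left out (adjusted p = 0.0596 to 0.0776).

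Of 23 tested cholesterol synthesis genes 19 rose, 20 adjusted over the list alone. Cyp51, which demethylates lanosterol, rose from 69.7 ± 0.239 to 97.0 ± 1.37 FPKM and Sqle, squalene epoxidase, from 29.1 ± 0.835 to 39.98 ± 1.22 FPKM. That list had adjusted p = 5.42e-08 by camera and adjusted p = 0.2 with an estimated correlation. In fatty acid synthesis 10 of 17 genes rose and 1 more fell adjusted over the list alone, with Fasn, the fatty acid synthase, at 58.6 ± 2.64 and 75.8 ± 2.92 FPKM and Elovl5, an elongase, at 32.0 ± 0.268 and 38.3 ± 0.933 FPKM. Camera gave adjusted p = 0.0121, and adjusted p = 0.2 with an estimated correlation. In fatty acid oxidation 8 of 19 genes rose and 1 fell, 9 and 1 adjusted over the list alone, with Cpt1a, which imports fatty acids into mitochondria, rising from 12.1 ± 0.538 to 15.8 ± 0.143 FPKM and Ech1 from 42.0 ± 1.98 to 51.7 ± 2.42 FPKM. This list was at the threshold (adjusted p = 0.0496, and adjusted p = 0.44 with an estimated correlation) and lost its call under 15 of 22 alternatives, among them leaving out control replicate 1 or 3 or acetate replicate 2 or 3 (adjusted p of up to 0.164 over the alternatives). In glycolysis 10 of 18 genes rose and 1 fell, 10 and 2 adjusted over the list alone, with Pfkl, a phosphofructokinase, rising from 26.9 ± 1.19 to 37.7 ± 1.68 FPKM and Tpi1 from 124.6 ± 4.86 to 185.7 ± 15.7 FPKM. Its adjusted p was 0.00531, and adjusted p = 0.35 with an estimated correlation.

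In oxidative phosphorylation 22 of 48 genes rose and 2 fell, with the same counts adjusted over the list alone. Uqcrfs1 of complex III rose from 80.8 ± 2.09 to 106.5 ± 3.62 FPKM and Cox7b of complex IV from 102.4 ± 0.338 to 126.3 ± 7.15 FPKM. Camera gave adjusted p = 0.000907, and adjusted p = 0.71 with an estimated correlation, and the call was lost with quantile normalization and with cyclic loess. In ribosome biogenesis 17 of 24 genes rose, also 17 adjusted over the list alone, among them Nop56 from 98.9 ± 1.14 to 132.0 ± 1.78 FPKM and Bop1 from 65.4 ± 2.67 to 92.5 ± 3.52 FPKM. That list had adjusted p = 7.48e-06, and adjusted p = 0.23 with an estimated correlation. Of 46 cytosolic ribosomal protein genes 4 rose, among them Rpl38 and Rpl37, both lost without control replicate 1 or 3 or acetate replicate 2 (adjusted p = 0.051 to 0.0673).

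Genes of acetate use were part of the panel. Slc16a1, a monocarboxylate transporter, rose from 71.4 ± 2.51 to 91.6 ± 2.70 FPKM and Acly, which makes cytosolic acetyl-CoA from citrate, from 93.5 ± 2.06 to 113.6 ± 3.35 FPKM. Acss1, the mitochondrial acetyl-CoA synthetase, fell from 1.37 ± 0.139 to 0.942 ± 0.026 FPKM (adjusted p = 0.0416), a call lost when any library was left out (adjusted p = 0.061 to 0.127). Its cytosolic counterpart Acss2 was below the filter, at 0.671 ± 0.0236 and 0.470 ± 0.106 FPKM, and did not pass when run with no filter (limma adjusted p = 0.148). Of 12 tested genes of acetate uptake and acetyl-CoA supply 6 rose and 1 fell, 8 and 2 adjusted over the list alone (camera adjusted p = 0.0856), led by the transporter Slc16a3 from 2.90 ± 0.203 to 5.63 ± 0.138 FPKM. None of the short-chain fatty acid receptor genes reached the filter, and no library held over 2 reads of Ffar2 or Ffar3. Tlr3 held at most 4 reads in any library, with group means of 0.0088 and 0.0046 FPKM. It was thus near 0 in both groups, and a difference in it was not detectable at this depth. Gzmk, which encodes granzyme K, was below the filter with a mean of 18 reads in each group, and did not pass when run with no filter (limma adjusted p = 0.986). Of 28 genes of histone acetylation and deacetylation 6 rose and 6 fell, 7 and 8 adjusted over the list alone, with Hat1, an acetyltransferase, rising by 0.38 on the log2 scale to 47.4 ± 2.86 FPKM and Sirt5 falling from 8.54 ± 0.376 to 6.57 ± 0.158 FPKM.

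**Figure D2:**
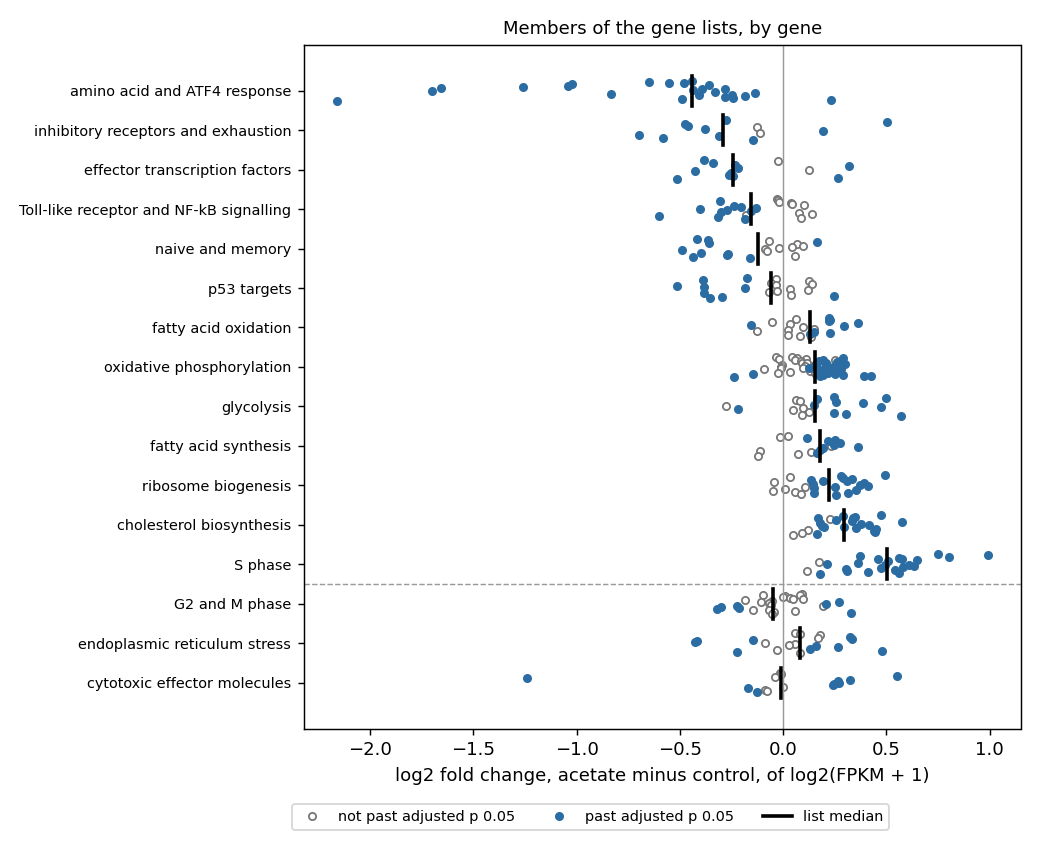
Log2 change (acetate minus control, of log2(FPKM + 1)) of each tested member of the 13 gene lists past the threshold, above the dashed line, and of 3 others below it. Filled points are genes past limma's threshold, open points are not, and black bars are list medians, from -0.44 for the amino acid and ATF4 list to 0.50 for the S phase list.

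Cytotoxic genes moved in both directions. Gzma, which encodes granzyme A and lies on chromosome 13 from 119139748 to 119146900, fell from 107.3 ± 4.16 to 45.0 ± 3.69 FPKM (limma adjusted p = 7.35e-05). Gzmb, which encodes granzyme B, rose (adjusted p = 0.00232), a call lost with no filter (adjusted p = 0.16) and with quantile normalization (adjusted p = 0.0803). Prf1, which encodes perforin, was at 111.0 ± 5.17 and 111.0 ± 3.27 FPKM (adjusted p = 0.995). Fasl was at 24.1 ± 0.653 and 23.4 ± 1.26 FPKM. Of 15 tested cytotoxic effector genes 6 rose and 3 fell, the same adjusted over the list alone, with Ctsw, a cathepsin of killer cells, rising from 39.0 ± 2.99 to 57.6 ± 2.91 FPKM. The list was not past the threshold (camera adjusted p = 0.791), and its median of -0.01 and mean of 0.01 differ in sign. Beside the fall of Gzma, the receptor genes Klrd1 and Klrk1, counted among natural killer cell markers, fell from 25.5 ± 1.09 to 17.4 ± 0.69 FPKM and from 4.93 ± 0.259 to 3.20 ± 0.472 FPKM, and Klrc1, below the filter and named after its values were seen, was at 0.909 ± 0.156 and 0.333 ± 0.107 FPKM. The natural killer cell receptor genes Ncr1 and Klrb1c, also named after their values were seen, held a mean of 3 and 5 reads in either group.

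Cytokine genes also divided. Ifng, which encodes interferon gamma, fell from 1118 ± 39.9 to 925.4 ± 18.4 FPKM and Tnf rose from 55.3 ± 0.554 to 69.9 ± 0.906 FPKM. The fall of Ifng had adjusted p = 0.00378 and missed the threshold without the filter on low values (adjusted p = 0.0566). Il2 rose from 3.88 ± 0.572 to 5.18 ± 0.727 FPKM (adjusted p = 0.0473), lost without control replicate 1 or 3 or acetate replicate 1 or 2 (adjusted p = 0.103 to 0.136). Of 18 secreted cytokine and chemokine genes 3 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 0.642), and the list's median of 0.04 and mean of -0.05 differ in sign. Tnfsf11, the ligand of RANK, fell from 41.5 ± 1.49 to 31.4 ± 0.624 FPKM.

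Of 12 tested genes of the inhibitory receptor and exhaustion list 8 fell and 2 rose, the same adjusted over the list alone, with camera adjusted p = 0.00531, and adjusted p = 0.2 with an estimated correlation. Tigit fell from 215.6 ± 12 to 143.6 ± 4.29 FPKM, Ctla4 from 40.1 ± 1.38 to 28.9 ± 1.57 FPKM, and Cd274, which encodes PD-L1, from 43.9 ± 1.17 to 31.3 ± 1.98 FPKM. Pdcd1, which encodes PD-1, fell from 45.7 ± 0.522 to 36.8 ± 2.19 FPKM. Cd160 rose from 6.51 ± 0.0576 to 9.63 ± 0.51 FPKM and Lag3 from 170.4 ± 3.91 to 194.9 ± 6.41 FPKM, the latter lost with quantile normalization (adjusted p = 0.083) and cyclic loess (adjusted p = 0.102). Havcr2 was at 4.30 ± 0.595 and 3.84 ± 0.246 FPKM and did not pass. The tested members of this list that are not receptor genes are the ligand gene Cd274 and 2 transcription factor genes named after their values were seen, Ikzf2, which fell from 12.6 ± 0.0933 to 9.48 ± 1.17 FPKM, and Nr4a2, at 11.6 ± 0.425 and 10.7 ± 0.496 FPKM without passing.

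Of 18 naive and memory genes 9 fell and 1 rose, the same adjusted over the list alone, with camera adjusted p = 0.00953, and adjusted p = 0.2 with an estimated correlation. Il7r, the receptor of interleukin 7, fell from 80.1 ± 2.34 to 56.8 ± 1.75 FPKM and the transcription factor gene Lef1 from 18.8 ± 0.787 to 14.1 ± 0.326 FPKM. Tcf7 fell from 134.9 ± 2.91 to 120.8 ± 2.75 FPKM, lost without acetate replicate 2 (adjusted p = 0.0518). Of 13 effector transcription factor genes 9 fell and 2 rose, the same adjusted over the list alone, with camera adjusted p = 0.0174, and adjusted p = 0.35 with an estimated correlation. Bhlhe40 fell from 130.5 ± 3.67 to 102.9 ± 2.13 FPKM, while Id2 rose from 77.3 ± 2.34 to 96.7 ± 1.78 FPKM and Tbx21, which encodes T-bet, from 21.0 ± 0.504 to 25.5 ± 0.944 FPKM. Eomes was at 40.5 ± 1.58 and 42.5 ± 0.725 FPKM and did not pass.

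Of 20 activation and costimulation genes 7 rose and 7 fell, the same adjusted over the list alone (camera adjusted p = 0.935). Slc3a2, an amino acid transporter chain, fell from 108.4 ± 3.02 to 79.9 ± 1.72 FPKM and Tnfrsf4, which encodes OX40, rose from 96.3 ± 3.01 to 131.7 ± 4.66 FPKM. Il2ra fell from 256.9 ± 4.17 to 231.1 ± 4.10 FPKM, lost without control replicate 3 (adjusted p = 0.0531) or acetate replicate 2 (adjusted p = 0.0536). Cd69 fell from 23.6 ± 1.62 to 20.6 ± 0.518 FPKM, lost without control replicate 2 or 3 or acetate replicate 1 or 2 (adjusted p = 0.0744 to 0.0855). Cd44 was at 45.1 ± 1.21 and 44.1 ± 1.43 FPKM without passing, and Cd8a rose from 308.4 ± 1.57 to 352.1 ± 12.3 FPKM, lost with cyclic loess (adjusted p = 0.0576).

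**Figure D3:**
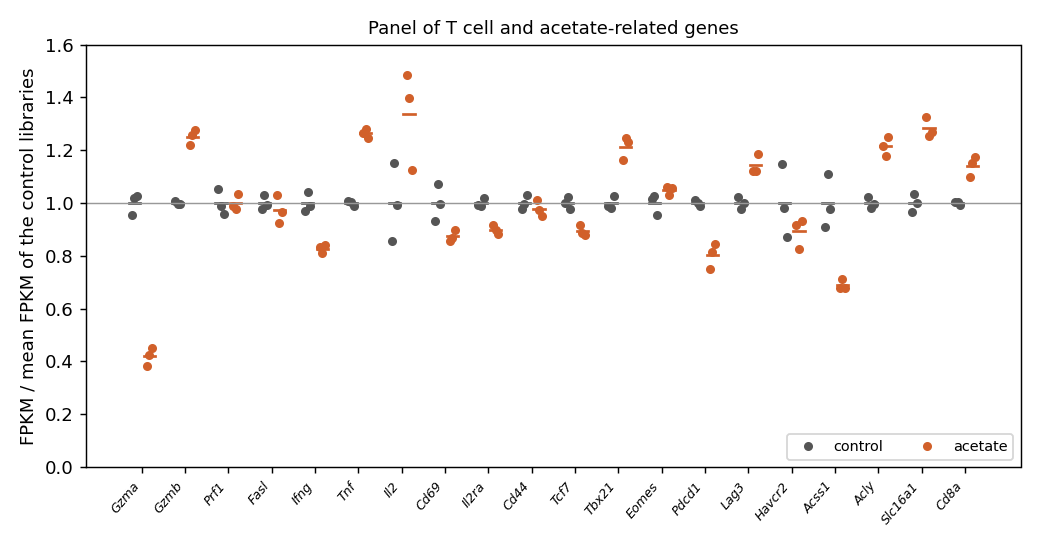
FPKM of each library divided by the mean of the 3 control libraries, for 20 panel genes that passed the filter. Points are libraries and bars are group means, and the acetate libraries lie furthest below control for Gzma, at a ratio of means of 0.419.

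Of 21 tested genes of Toll-like receptor and NF-kB signalling 11 fell, also 11 adjusted over the list alone, and 10 did not pass. The list had camera adjusted p = 0.00635, and adjusted p = 0.2 with an estimated correlation. Tnfaip3, which encodes the NF-kB inhibitor A20, fell from 30.6 ± 0.345 to 19.8 ± 1.5 FPKM, Traf1 from 70.9 ± 1.10 to 56.8 ± 0.873 FPKM and Nfkb1, an NF-kB subunit gene, from 73.5 ± 2.20 to 62.1 ± 0.703 FPKM. Among members that did not pass and are named after their values were seen, the Toll-like receptor adaptor genes Myd88 and Ticam1 were at 24.7 ± 1.01 and 26.6 ± 1.63 FPKM and at 7.46 ± 0.838 and 8.30 ± 0.365 FPKM, and Tlr2 at 2.44 ± 0.283 and 2.05 ± 0.413 FPKM. Of 19 p53 target genes 8 fell and 1 rose, the same adjusted over the list alone, with Fas, a death receptor, falling from 53.3 ± 2.09 to 37.0 ± 1.08 FPKM and Bbc3, which encodes PUMA, from 41.3 ± 0.618 to 31.4 ± 1.78 FPKM. That list was at the threshold (adjusted p = 0.0496, and adjusted p = 0.25 with an estimated correlation) and lost its call without control replicate 2 or 3 or acetate replicate 2 or 3 (adjusted p of up to 0.0785 over the alternatives).

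The lists in this paragraph were not past the threshold by camera, and counts adjusted over the list alone follow where they differ. Of 22 T cell receptor signalling genes 6 rose and 3 fell. Of 15 chemokine receptor and integrin genes 7 rose and 2 fell (7 and 3), with Itgae, which encodes CD103, rising from 9.10 ± 0.497 to 15.8 ± 0.774 FPKM and Cxcr6 from 2.78 ± 0.218 to 5.47 ± 0.485 FPKM. Of 19 IL-2 and STAT5 response genes 5 rose and 5 fell (5 and 6), with Il18r1 falling from 11.1 ± 0.625 to 6.89 ± 0.454 FPKM. Of 20 type I interferon response genes 2 rose and 5 fell, with Isg15 falling from 30.1 ± 1.28 to 16.3 ± 1.58 FPKM, and of 19 interferon gamma response and antigen presentation genes 3 rose and 6 fell, with Gbp2 falling from 24.1 ± 0.785 to 18.4 ± 0.482 FPKM. Of 19 endoplasmic reticulum stress genes 6 rose and 4 fell (7 and 4), with Herpud1 falling from 38.4 ± 1.42 to 28.3 ± 0.837 FPKM and the chaperone gene Dnajb11 rising from 43.9 ± 1.83 to 55.2 ± 0.612 FPKM. Of 15 hypoxia targets 8 rose and 3 fell, with Egln1 rising from 28.5 ± 1.06 to 38.6 ± 0.891 FPKM. Of 17 NRF2 and oxidative stress genes 8 rose and 3 fell, with Pgd rising from 18.8 ± 0.798 to 25.2 ± 0.964 FPKM. Of 21 tricarboxylic acid cycle genes 6 rose and 3 fell (9 and 3), of 14 heat shock genes 4 rose and 3 fell, and of 22 lysosome and autophagy genes 7 rose and 2 fell (7 and 4). Of 17 apoptosis regulators 4 rose and 4 fell (5 and 4; median 0.001 and mean -0.018, which differ in sign), with Cflar, a caspase-8 inhibitor, falling from 29.1 ± 1.88 to 19.5 ± 0.879 FPKM. The 46 ribosomal protein genes had camera adjusted p = 0.0856, and adjusted over the list alone their 4 calls were lost.

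Of 19 tested markers of cells other than CD8+ T cells, over 6 lists, 8 fell, 1 rose and 10 did not pass. Among 4 tested B cell markers 1 rose and 1 fell, Ighm from 53.5 ± 2.68 to 73.6 ± 4.79 FPKM and Spib from 49.8 ± 2.24 to 29.2 ± 0.761 FPKM, and the list's median of 0.06 and mean of -0.04 differ in sign. Among 4 CD4 and regulatory T cell markers 2 fell, led by Zbtb7b from 13.03 ± 0.17 to 7.12 ± 0.388 FPKM, and Cd4 itself, below the filter and named after its values were seen, was at 0.641 ± 0.119 and 0.944 ± 0.138 FPKM. Among 4 myeloid markers 1 fell, Apoe from 6.69 ± 0.677 to 4.48 ± 0.375 FPKM, and among 4 dendritic cell markers 1 fell, Zbtb46 from 2.16 ± 0.0704 to 1.181 ± 0.119 FPKM. Of the natural killer and gamma delta T cell markers 2 were tested and both fell, as given beside Gzma, and of the erythroid markers 1 was tested, Car2, which fell from 5.92 ± 0.153 to 4.13 ± 0.325 FPKM. Of the mitochondrial genome transcripts 1 symbol was in the table, mt-Nd6, named after its values were seen and listed at 0 in all 6 libraries. With no rows on the mitochondrial chromosome, these transcripts were not compared.

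In all, 13 of 37 lists passed the threshold by camera, 7 higher and 6 lower. With an estimated correlation 0 did (8 at an unadjusted p under 0.05), and fry called 21. The estimate was below the preset 0.01 for p53 targets (-0.041), inhibitory receptors and exhaustion (-0.038), fatty acid synthesis (-0.01) and Toll-like receptor and NF-kB signalling (0.0057). A higher correlation between genes therefore cannot account for the loss of these lists. For the others past the threshold it ran from 0.011 for naive and memory genes to 0.62 for oxidative phosphorylation. Changes also followed abundance, with a median log2 change of -0.05 in decile 1 of mean abundance, the lowest, and 0.11 in decile 10.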

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

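Of the alternatives here, voom, cyclic loess, the GC and length correction, the extended lists, lists and single genes over protein-coding genes, and the run without pseudogenes and unnamed genes were chosen after seeing the data. Rescaling to TPM, which multiplies each library by 1 factor, took the median log2 change of all genes tested from 0.021 to -0.05 and so gave 1396 higher genes against 2393, with 2443 lower. Requiring a log2 change of at least 1 left 11 higher and 38 lower genes by its construction. Lists past the threshold numbered 13, 0 with an estimated correlation and 21 with fry, which does not compare a list with other genes. The run with an estimated correlation also lost lists whose estimate was below the preset 0.01. Its count therefore does not measure correlation between genes alone, and reflects its fewer degrees of freedom as well. Leaving out 1 library gave 1710 to 2290 higher genes, 1359 to 1697 lower genes and 11 to 14 lists. With the replicate number as a block, limma called 2052 higher and 1548 lower genes and 12 lists. Same-numbered libraries did not deviate together (correlations -0.054, 0.026 and -0.039), and not every library correlated best with its own number, so the numbers were not taken to pair samples. Voom on the recovered reads called 2700 higher and 2094 lower genes, of which 4061 were among the 4229 main calls in the same direction.

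Of the 159 genes followed, 3231 of the values under alternatives kept their direction and side of the threshold, 72 kept their direction and lost the call, and 11 changed sign. The sign changes were in genes that had not passed. Prf1, at 0 as deposited and so with no direction to lose, was -0.02 with median centring and -0.075 as TPM, close to the shift of all genes under each, and -0.093 with quantile normalization, -0.01 with array weights, -0.098 with cyclic loess, -0.037 with the GC and length correction, and -0.028 to 0.037 with a library left out. Eomes was -0.005 as TPM and -0.011 with cyclic loess. Apart from the common shifts under median centring and TPM, the cause was not tested. Of the 13 lists, 10 kept their call under all 22 alternatives with the preset correlation, oxidative phosphorylation lost it under 2, p53 targets under 7 and fatty acid oxidation under 15. DESeq2 and edgeR were planned for counts and were not run. Ffar2, Ffar3 and Tlr3 were near 0, with group means of at most 0.011 FPKM, and held too few reads for a difference to be detected.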

Other observations

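The lists and genes in this paragraph were chosen after their values were seen. Of 20 cytosolic aminoacyl-tRNA synthetase genes, whose products load amino acids onto tRNA, 12 fell and 3 rose, among them Wars from 57.3 ± 0.521 to 37.4 ± 1.16 FPKM and Nars from 227.7 ± 4.74 to 150.1 ± 6.07 FPKM (limma adjusted p = 9.89e-05 and 0.000128, n = 3 per group). The list had camera adjusted p = 2.97e-05 over the 4 lists added, and adjusted p = 0.32 with an estimated correlation. It shares 2 genes with the amino acid and ATF4 list, and without them 10 of 18 fell and 3 rose (camera adjusted p = 0.000457, and adjusted p = 0.36 with an estimated correlation). Of 17 mitochondrial synthetase genes 2 rose and 3 fell (adjusted p = 0.584). Of 19 amino acid transporter genes 12 fell and 2 rose, with Slc38a7 falling from 8.82 ± 0.61 to 4.73 ± 0.157 FPKM, but 9 of the 19 were in one of the fixed lists or among the 12 largest falls. Of the other 10 genes 4 fell and 1 rose, and these were not past the threshold as a list (camera adjusted p = 0.139). Of 29 proteasome subunit genes 17 rose, such as Psmd12 from 60.0 ± 1.86 to 74.3 ± 2.58 FPKM (camera adjusted p = 2.97e-05, and adjusted p = 0.38 with an estimated correlation). Their median log2 change was 0.169, but abundant genes rose in general, with medians of 0.079 and 0.112 in deciles 9 and 10 of abundance. The added lists were not run with cyclic loess or quantile normalization.

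Every test in the paragraphs that follow was chosen only after the result it bears on was seen. The labels give no batch. They give 72 h of culture for both groups, but the design text speaks of cells before and after acetate. Handling or time in culture that differed between the groups therefore cannot be separated from acetate. With 3 libraries per group there are 10 splits of the 6 libraries, too few for a share under 0.05. The real split called 4229 genes and 1 of the 10 splits gave as many, the highest other being 0 genes by limma with 308 at an unadjusted p under 0.05. It called 13 lists, which 1 of the 10 splits reached, and the other splits called 3 to 8 lists each, with 0 genes called. Every other split mixes control and acetate libraries in both of its groups. The difference between acetate and control then widens the spread within groups, so few genes could be called and the comparison decides nothing.

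The fall of the amino acid and ATF4 list, at a median of -0.44, was not removed by cyclic loess, which left -0.517, or by correcting for GC content and length, which left -0.451. These argue against a scaling, abundance, GC or length trend as its whole cause. A general fall of the listed endoplasmic reticulum stress genes is also argued against, since 6 rose and 4 fell, at a median of 0.081 with an SD of 0.238 over members. Atf4, Ddit3 and Trib3 are not in that list but in the amino acid and ATF4 list. The comparison therefore cannot show which stress lowered the ATF4 genes, and lower endoplasmic reticulum stress signalling through ATF4 stays open. A lower amino acid or other ATF4 response to acetate is a hypothesis drawn from these same data, and no test here was of acetate as its cause. An untested difference in medium, time in culture or handling stays open.

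The S phase list rose by a median of 0.50 while the G2 and M phase list had a median of -0.049 with an SD of 0.164, which argues against a larger share of cells in every phase of the cycle. The S phase median was 0.436 after cyclic loess and 0.475 after the GC and length correction, which argues against these trends as its whole cause. A shift in cell cycle timing may account for the rise, but no measurement of cell cycle phase was analysed here, and a difference in time in culture stays open beside this hypothesis.

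Gzma fell while Gzmb rose, and its log2 change was -1.329 after cyclic loess against -1.238, which argues against a scaling trend. A loss of natural killer cells stays open, although positive magnetic selection of CD8+ cells would leave most of them out and their receptor genes Ncr1 and Klrb1c held a mean of 3 and 5 reads in either group, while Gzma fell from 107.3 ± 4.16 to 45.0 ± 3.69 FPKM. Over the 7 members of the natural killer and gamma delta T cell list with at least 10 mean control reads, the median ratio of acetate to control was 0.684, from 0.366 for Klrc1 to 1.687 for Sox13, against 0.419 for Gzma. Ncr1 and Klrb1c are too near the floor, and members other than Klrd1 and Klrk1 hold too few reads, to exclude such a loss. CD8+ T cells can also express Klrd1, Klrk1 and Klrc1, so a smaller share of natural killer cells and a change within the CD8+ T cells cannot be told apart.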
